A study of Mus musculus with 8 samples.

How the data were processed

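RNA from 8 mouse hearts was sequenced, 4 from animals given an adeno-associated virus carrying the miR-29a primary transcript with GFP and 4 from animals given the GFP virus alone. Per the labels' protocols and the series' design text, libraries were made from 500 ng of RNA with a stranded mRNA kit, RNA integrity numbers were above 7.5, and reads were paired and 50 bases long. The design text states 11 M reads per library with 90% aligned. Per the submitters' processing notes and the design text, reads were pseudoaligned with kallisto 0.43.1 to GRCm38 and summarised per Ensembl gene with sleuth 0.30.0. The Ensembl release and the authors' filter on low genes are not given in the sources used here.

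The deposited table of values per heart holds a signal in scaled reads per base, that is, estimated reads divided by gene length and rescaled between libraries by the authors, per the series' design text and per the labels. These values are neither counts nor values per 1000000 reads. The 8 columns summed to different totals, and across genes the factor that turned a value back into the authors' own scale followed transcript length (r = 0.988 across genes, which are not independent replicates). The authors' second deposited table holds the results of their own comparison, with effects as a natural log fold change and with Wald and likelihood ratio p-values and q-values. Multiplying each gene's values by 1 factor per gene, set from the authors' deposited mean, adding 0.5 and taking the natural log gave the deposited effects back with a median absolute difference of 0.00258 and a 99th percentile of 0.0055. The table listed 55416 gene identifiers, of which 36035 had values, and 14373 of these were 0 in each heart. All 8 value columns matched a sample's label.

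No count per gene was used, so no counting interval could be given. The spacing of the low values gave a rough depth of 5.94 to 8.92 M reads per heart, but only 53.3% to 70.7% of the low values lay within 0.1 of a whole number of reads. Whole reads were therefore not recovered and no count model was run.

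Groups were taken from the treatment label. Replicate numbers follow the order of deposit and pair nothing. Values were used as deposited, as log2(value + 0.497), where the pseudocount is 0.5 per 1000000 of the median library total. Genes with a mean of at least 1 per 1000000 of the library total were tested, which left 11970. The test was limma 3.58.1 (R 4.3.3; lmFit, then eBayes with a trend), miR-29a against GFP, two-sided, with Benjamini-Hochberg adjusted p under 0.05 called changed. A fold change is on the log2(value + pseudocount) scale and understates the change of low genes. Tested on simulated data on the 11970 genes of this comparison, the fit recovered 28 of 67 genes changed by 0.5 on the log2 scale, 57 of 67 changed by 1 and 65 of 66 changed by 2, and 3 of its 153 calls were unchanged genes. In a further simulation of the same kind, 3 of 200 unshifted lists of 25 genes had p under 0.05. Simulated genes varied independently of each other, so this cannot show how a list test fares with correlated genes. The noise was normal, with each gene's variance taken from the limma fit and equal in each heart. The recovery and false calls therefore hold only where the fit's own assumptions hold.

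Before the data were examined, 37 gene lists were fixed from textbook knowledge, and the 31 with at least 5 members tested were compared with limma's camera at its preset correlation of 0.01, adjusted over the 31 lists. Camera asks whether a list's genes shift relative to other genes. Fry asks whether a list's genes move on balance in 1 direction, and compares them with no other genes. Each list was also tested with an estimated correlation, with fry, and as its mean log2 value per heart in a two-sided exact permutation test of 70 arrangements, whose smallest p is 0.0286. Sites for the miR-29 seed were searched in the longest annotated 3' UTR of each gene in GENCODE release M21 (GRCm38): the 8mer TGGTGCTA, the 7mer-m8 TGGTGCT and the 7mer-A1 GGTGCTA. A 3' UTR was annotated for 96.1% of tested genes, and the seed test ran on these 11505 genes. The miR-29 heptamer was set beside 139 control heptamers of the same base composition.

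The genes named were set by a rule fixed at the same time. It takes the 10 rising and 10 falling genes with the largest log2 fold change among called genes with a mean of at least 5 per 1000000 and no overlap between the hearts of the groups. It adds up to 4 members with the smallest p in each list described by its members. That these are the lists that were called or held a changed member was chosen after the values were seen. It adds the miR-29 genes and Col1a1, Col3a1, Eln, Atp2a2, Pln, Ryr2, Slc8a1, Casq2 and Ttn whatever their result. A few genes that the rule names are not reported here. Alternatives were the pseudocount, the filter, rescaling by TMM or median-of-ratios factors, no trend, array weights, a term for the first part of the animal number, each heart left out, the authors' q-values, other list tests and other site definitions. Chosen after seeing the data were rescaling to the same total, with and without mitochondrially encoded genes, the authors' observation scale, and centring the values for the seed test within bins of abundance, 3' UTR GC content and 3' UTR length. Transcript stretches of 50 bases shared between genes were counted in the same annotation.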

Results

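Gene expression was measured by RNA sequencing in the hearts of 8 male C57BL6/J mice. The animals were 3 to 5 weeks old when a virus was injected into the jugular vein, and hearts were taken 3 weeks later. The virus was AAV2/9, an adeno-associated virus vector that reaches heart muscle. In 4 animals it carried the primary transcript of miR-29a, a microRNA known to repress collagen and other matrix transcripts, together with GFP, and in 4 controls it carried GFP alone. The comparison asks how raised miR-29a changes the heart's transcripts, and the study's title names myocardial compliance, calcium handling and the extracellular matrix. The deposited values summed to 939974 ± 29362 per GFP heart and 1055022 ± 31130 per miR-29a heart (SD, n = 4 each), with no overlap between the groups (exact permutation test, two-sided, p = 0.0286, the smallest these 8 hearts allow). Pearson's correlation of log2 values lay between 0.974 and 0.979 for pairs of GFP hearts, between 0.973 and 0.977 for pairs of miR-29a hearts and between 0.969 and 0.977 across the groups, each across genes. The first principal component held 20.5% of the variance and separated the groups, from -19.0 to -10.3 in GFP hearts and from 8.46 to 20.6 in miR-29a hearts. The miR-29 genes themselves (Mir29a, Mir29b-1, Mir29b-2 and Mir29c) were listed without values, so the level of the microRNA was not measured here.

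Hearts given miR-29a differed from GFP hearts in 296 of 11970 genes tested, with 111 higher and 185 lower (limma, adjusted p under 0.05). The largest decrease was in Acta1, the alpha-actin of skeletal muscle (chromosome 8, 123891769 to 123894751, GRCm38), at 183 ± 48.8 scaled reads per base in GFP hearts and 40.7 ± 13.9 in miR-29a hearts (SD, n = 4 each), 4.50-fold lower (log2 fold change -2.17 ± 0.22 SE, limma adjusted p = 0.00491). Bdh1, a mitochondrial enzyme of ketone body metabolism (chromosome 16, 31422280 to 31458901), was 2.94-fold lower, from 25.1 ± 3.97 to 8.37 ± 2.34 (limma adjusted p = 0.00605). Casq1, the calsequestrin of skeletal muscle, was 2.35-fold lower. Trim7 fell by 1.28 on the log2 scale, Tmem82 by 1.29 and Lypd8l by 1.46. Dusp18, a dual specificity phosphatase, was 2.09-fold lower. Nqo1, a quinone reductase of the oxidative stress response, was 1.94-fold lower, Kcnip2, an accessory subunit of the cardiac transient outward potassium channel, 1.92-fold lower, and Ung, a uracil-DNA glycosylase, 1.90-fold lower.

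Among rising genes, Nme1, a nucleoside diphosphate kinase (chromosome 11, 93956979 to 93968521), was at 6.86 ± 1.71 in GFP hearts and 17.2 ± 2.15 in miR-29a hearts, 2.44-fold higher (log2 fold change 1.29 ± 0.15 SE, limma adjusted p = 0.00724). Atcay was 2.16-fold higher and Armh4 2.02-fold higher. Tfrc, the transferrin receptor that takes up iron, was 1.91-fold higher, and Aldh1b1, a mitochondrial aldehyde dehydrogenase, 1.86-fold higher. Kcne1, a subunit of the slow delayed rectifier potassium channel, was 1.80-fold higher, Tatdn3 1.78-fold, and Tmem35a and Efnb3, an ephrin ligand, each 1.69-fold. The largest log2 fold change, 4.51 ± 0.45 SE, belonged to Gm10241, a processed pseudogene that was listed at 0 in 3 GFP hearts and at 1.83 in GFP replicate 1, against 12.7, 17.0, 18.7 and 16.9 in the miR-29a hearts. Each of its 237 stretches of 50 bases also occurs in Sumo2, so this value is uncertain. Sumo2 was at 87.3 ± 1.83 in GFP hearts and 81.1 ± 5.40 in miR-29a hearts (limma adjusted p = 0.418). Of the stretches of Nme1, 11.1% also occur in the overlapping gene Gm20390.

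In 293 of the 296 changed genes the hearts of the groups did not overlap. These genes were called on the same hearts, which largely fixes that outcome, so it is no separate support. Over all tested genes the share without overlap was 10.5%, where chance gives 2.86%. Rescaling each heart to the same total gave a median log2 fold change of -0.15, against 0.00469 with the values as deposited, and 58 higher and 1221 lower genes. Leaving out GFP replicate 2, 3 or 4 lowered the count to 70, 128 or 55, and leaving out miR-29a replicate 1, 3 or 4 lowered it to 95, 75 or 94. Of the 20 genes named above for the size of their change, 12 passed the threshold with each heart left out, and the exceptions were Atcay, Armh4, Tfrc, Aldh1b1, Kcne1, Tmem35a, Lypd8l and Kcnip2. With a term for the animal series, Tfrc did not pass (adjusted p = 0.0635). Of the genes of the matrix, muscle, metabolic and marker lists described below, Col4a5, Trim63 and Cav3 passed with each heart left out, as did Acta1 and Casq1, and the other changed members that are named did not.

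**Figure D1:**
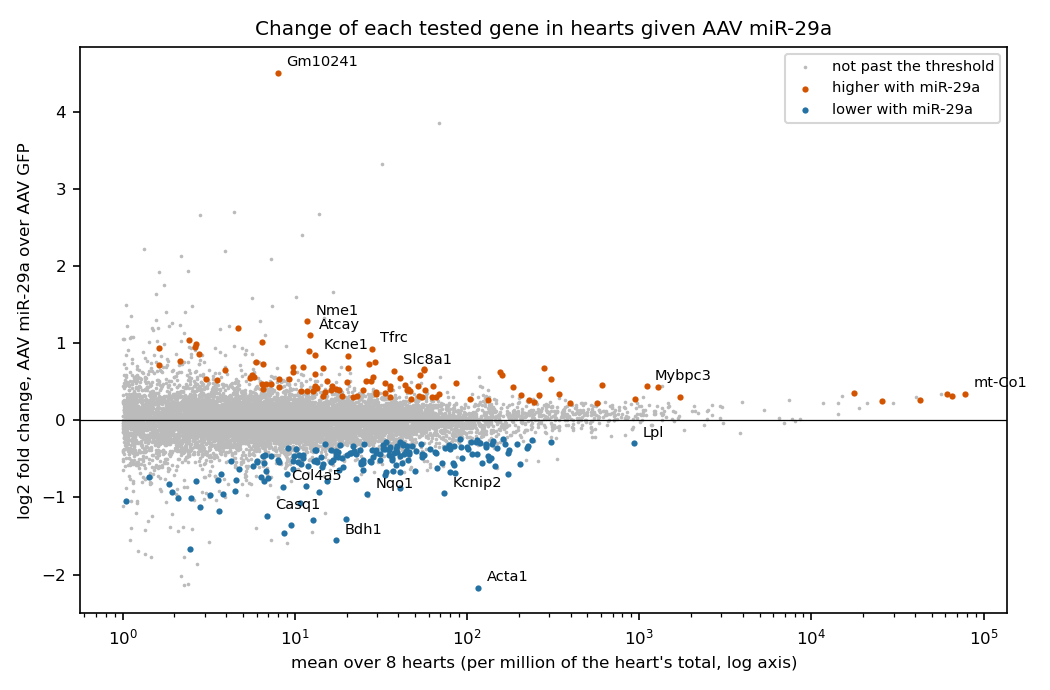
Log2 fold change of each of 11970 tested genes (AAV miR-29a over AAV GFP, vertical axis) against its mean abundance per 1000000 of a heart's total (horizontal log axis). The 111 higher and 185 lower genes are coloured, and Acta1 lies lowest among the changed genes at -2.17.

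Of the matrix genes, a basement membrane collagen chain fell while the fibrillar collagens did not pass the test. Col4a5 (chromosome X, 141475385 to 141689234), a type IV collagen chain with 3 miR-29 8mer sites in its 3' UTR, went from 10.9 ± 1.29 in GFP hearts to 5.74 ± 0.383 in miR-29a hearts, 1.81-fold lower (limma adjusted p = 0.00605). It was the only changed gene of 22 collagens tested, with 0 risen, 1 fallen and 21 not past the test. Col1a1, which encodes a chain of type I collagen, had a log2 fold change of 0.13 (95% interval -0.07 to 0.34), Col3a1, of type III collagen, 0.11 (-0.11 to 0.32), and Eln, elastin, 0.03 (-0.23 to 0.29). Col4a2 was at -0.30 (adjusted p = 0.146), Col4a1 at -0.18 (adjusted p = 0.415) and Col4a3 at 0.65 (adjusted p = 0.163), by limma. The collagen list did not pass the test of a shift relative to other genes (camera adjusted p = 0.982). Of 23 matrix genes known as miR-29 targets, Col4a5 alone fell and 0 rose (camera adjusted p = 0.887). In both lists 1 gene fell and 0 rose when adjusted over the list alone. For the collagens the median and mean changes were 0.05 and 0.01 while camera's sign was down. For the matrix targets the median was 0.06 and the mean -0.01. GFP replicate 3 had the highest mean log2 value of the GFP hearts for both lists. Leaving it out turned camera's sign up for both, and neither passed (adjusted p = 0.236 for each).

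Of 21 basement membrane genes, 2 fell and 0 rose: Col4a5 and Lama5, a laminin chain that was 1.59-fold lower (adjusted over the list alone 2 fell; camera adjusted p = 0.219). Of 25 genes for elastic fibres and crosslinking, Fbln1, an elastic fibre protein, fell 1.34-fold and Serpinh1, the collagen chaperone, 1.35-fold, and 0 rose. Adjusted over the list alone, 5 fell and 1 rose (camera adjusted p = 0.166). Pcolce, at a log2 fold change of 0.35, and Plod1, at -0.26, did not pass over all genes. Of 18 matrix proteases and inhibitors, Timp4 fell 1.42-fold and 0 rose, and adjusted over the list alone 2 fell and 1 rose (camera adjusted p = 0.166). Timp1 was at 1.22 on the log2 scale with a limma adjusted p of 0.0681, Ctsl at -0.30 and Ctsk at -0.40. None of 23 proteoglycan and matricellular genes passed, over all genes or over the list alone (camera adjusted p = 0.176).

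Of 27 other known miR-29 targets, 3 fell and 0 rose. Trim63, a muscle ubiquitin ligase, was 1.49-fold lower (98.3 ± 3.74 to 66.1 ± 6.55; limma adjusted p = 0.00864), Dnmt3a, a DNA methyltransferase, 1.42-fold lower (adjusted p = 0.0392; past in 0 of the 8 fits with a heart left out, adjusted p up to 0.104, and not past with a term for the animal series, 0.0655), and Lpl, lipoprotein lipase, 1.22-fold lower (adjusted p = 0.0277). Hbp1 was at -0.30 on the log2 scale (adjusted p = 0.0679). Adjusted over the list alone, 5 fell. The list did not pass as a whole (camera adjusted p = 0.166), and it did when GFP replicate 1 was left out (adjusted p = 0.0464). Its median change was 0.01 and its mean -0.06. Of 13 DNA methylation genes, Dnmt3a fell, and adjusted over the list alone 2 fell (camera adjusted p = 0.210). Mbd1 was at -0.51, Gadd45a at -0.41 and Dnmt1 at 0.18 on the log2 scale, none past the test.

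Calcium handling genes moved in both directions. Of 47 tested, 2 rose, 2 fell and 43 did not pass, and adjusted over the list alone 4 rose and 2 fell (camera adjusted p = 0.219). Slc8a1, the sodium-calcium exchanger (chromosome 17, 81373105 to 81738377), went from 29.5 ± 3.83 to 46.5 ± 6.65, 1.57-fold higher (limma adjusted p = 0.0277), and passed in 3 of the 8 fits with a heart left out (adjusted p up to 0.0787). Rcan1, an inhibitor of calcineurin, was 1.42-fold higher (past in 2 of the 8 fits, adjusted p up to 0.0959). Casq1 was 2.35-fold lower, from 9.49 ± 1.18 to 3.82 ± 0.952, and Asph, whose products include the sarcoplasmic reticulum protein junctin, 1.28-fold lower (past in 1 of the 8 fits, adjusted p up to 0.0951). Casq2, the cardiac calsequestrin, was at 337 ± 22.7 and 405 ± 32.4, a log2 fold change of 0.27 that did not pass (adjusted p = 0.0853). Atp2a2, the calcium pump of the sarcoplasmic reticulum, was at -0.04 (95% interval -0.16 to 0.08), its regulator Pln at 0.07 (-0.04 to 0.18) and the calcium release channel Ryr2 at 0.19 (0.02 to 0.37; adjusted p = 0.258).

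**Figure D2:**
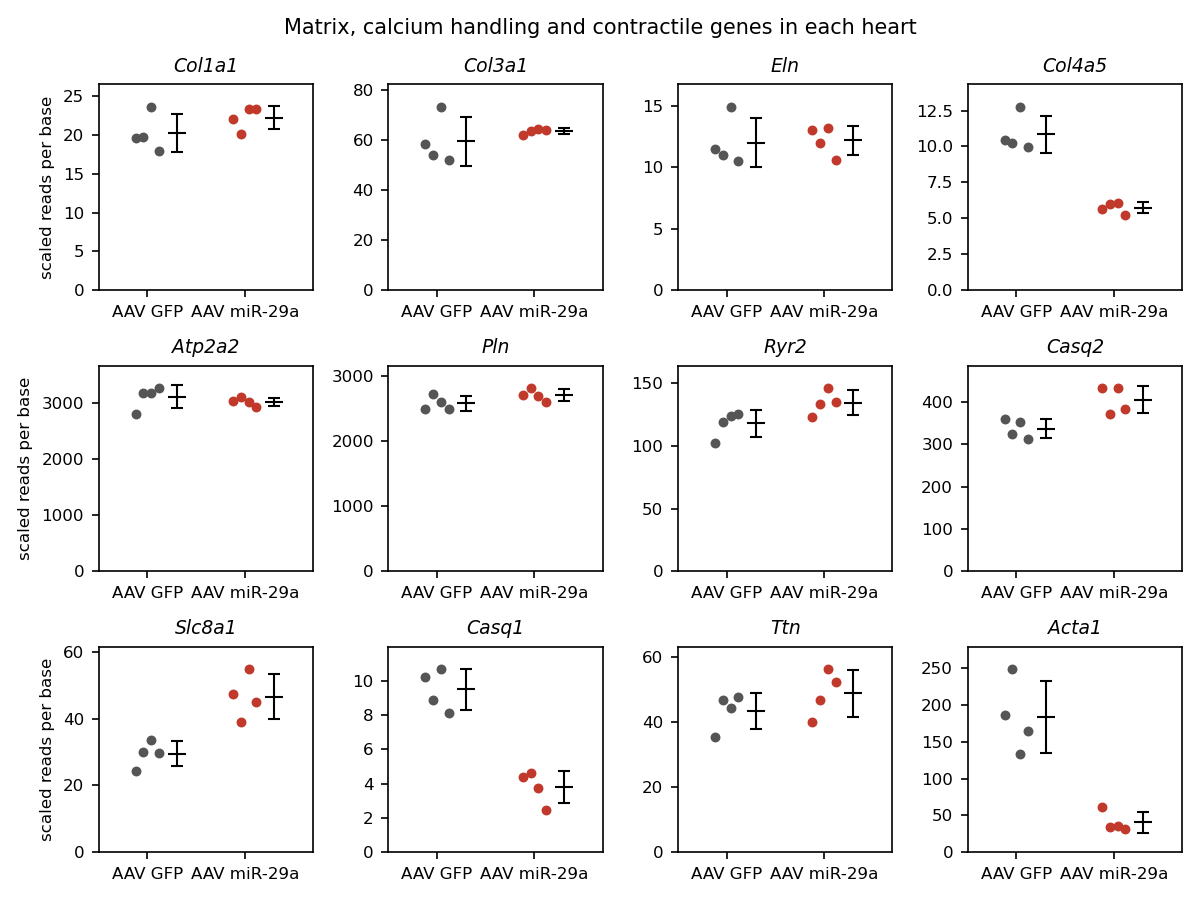
Scaled reads per base (vertical axes, from 0) of 12 matrix, calcium handling and contractile genes, with 1 point per heart and the group mean ± SD (n = 4) beside the points. Col4a5, Casq1 and Acta1 were lower, and Slc8a1 and Casq2 higher, in each miR-29a heart than in any GFP heart. Of these, Casq2 did not pass the test.

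Ion channel and contractile genes also moved both ways. Of 31 ion channel and junction genes, 2 rose and 4 fell, and adjusted over the list alone 3 rose and 6 fell (camera adjusted p = 0.176). Kcne1 was 1.80-fold higher, while Cav3, a caveolin of muscle, was 1.58-fold lower and Kcnip2 1.92-fold lower. Of 32 sarcomere genes, Mybpc3, cardiac myosin-binding protein C, rose 1.36-fold and Acta1 fell, and adjusted over the list alone 5 rose and 1 fell (camera adjusted p = 0.0869). Ttn, the giant spring protein titin, was at 43.6 ± 5.54 and 48.9 ± 7.17, a log2 fold change of 0.16 (95% interval -0.11 to 0.43). Myl2 was at 0.32 and did not pass the test. Of 20 cardiac stress genes, Rcan1, Ccng1 (1.26-fold) and Hspb7 (1.21-fold) rose and Acta1 fell, and adjusted over the list alone 7 rose and 3 fell (camera adjusted p = 0.166). With each heart rescaled to the same total, Rcan1, Ccng1 and Hspb7 did not pass (adjusted p = 0.0521, 0.113 and 0.149), and with a term for the animal series Rcan1 (0.0525) and Hspb7 (0.0514) did not.

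Mitochondrially encoded transcripts were higher with miR-29a. They made up 41.9 ± 2.08% of the summed values in GFP hearts and 45.5 ± 0.790% in miR-29a hearts (SD, n = 4 each), with no overlap (exact permutation test, two-sided, p = 0.0286, the smallest possible). Within animal series 2996 the share was 38.8% and 43.1% in GFP hearts and 44.8%, 44.9% and 45.7% in miR-29a hearts, and within series 2997 it was 42.2% and 43.3% against 46.5%. Of 13 genes, 6 rose and 0 fell, and adjusted over the list alone 11 rose (camera adjusted p = 6.02e-11). The adjusted p with an estimated correlation was 0.418. Mt-Co1 and mt-Co2, subunits of cytochrome oxidase, were each 1.27-fold higher, mt-Nd3, of complex I, 1.28-fold and mt-Nd1 1.19-fold, which are log2 fold changes of 0.35, 0.34, 0.35 and 0.25. With the same total in each heart these were 0.18, 0.17, 0.19 and 0.09. Annotated pseudogenes hold each 50-base stretch of mt-Co2, 98.0% of those of mt-Nd3 and 51.1% of those of mt-Co1, so these values are uncertain. Of 48 nuclear genes for oxidative phosphorylation, Sdha, of succinate dehydrogenase, rose 1.17-fold and 0 fell, and adjusted over the list alone 9 rose and 0 fell. That list's call was up with camera (adjusted p = 2.82e-07), its adjusted p with an estimated correlation was 0.650, and with hearts rescaled to the same total the sign was down (adjusted p = 0.784). Atp5b was at 0.24, Ndufa10 at 0.22 and Ndufs1 at 0.19 on the log2 scale, none past the test over all genes. With the same total in each heart, Sdha (adjusted p = 0.388) and mt-Nd1 (0.112) did not pass, and with a heart left out each passed in 1 of the 8 fits (adjusted p up to 0.103 and 0.0887). Of 19 genes for mitochondrial biogenesis none passed over all genes or over the list alone (camera adjusted p = 0.361).

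Genes of fatty acid use included 5 that fell and 0 that rose among 38 tested (adjusted over the list alone, 6 fell; camera adjusted p = 0.235; median 0.02 and mean -0.06). Slc25a20, the carnitine carrier, was 1.27-fold lower, Cpt2, carnitine palmitoyltransferase, 1.22-fold, Lpl 1.22-fold, and Pdk4, a kinase that restrains pyruvate dehydrogenase, 1.38-fold. With a heart left out, Slc25a20, Cpt2 and Pdk4 passed in 1 of the 8 fits each and Lpl in 2 (adjusted p up to 0.121, 0.127, 0.113 and 0.0866). Of 29 genes of glucose use, Eno3, the muscle enolase, rose 1.35-fold and Pgam1, phosphoglycerate mutase, 1.59-fold, while Pdk4 fell, and adjusted over the list alone 6 rose and 4 fell (camera adjusted p = 0.472). Of the stretches of Pgam1, 36.2% also occur in the pseudogene Pgam1-ps2. Ldha was at 0.23 on the log2 scale and did not pass. With a term for the animal series, Pdk4 (adjusted p = 0.0635) and Pgam1 (0.0734) did not pass.

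Genes of the unfolded protein and heat shock responses were lower as a list. Of 21 tested, Hspa5, the chaperone of the endoplasmic reticulum, fell 1.23-fold and 0 rose over all genes, and adjusted over the list alone 8 fell and 0 rose (camera adjusted p = 0.00173; adjusted p = 0.40004 with an estimated correlation). The log2 fold changes of Hsp90b1, Herpud1 and Calr were -0.27, -0.35 and -0.30, which did not pass over all genes. Markers of macrophages were lower too. Of 20 tested, C1qb and C1qc, subunits of complement C1q, fell by 0.33 and 0.34 on the log2 scale and 0 rose, and adjusted over the list alone 5 fell (camera adjusted p = 0.000590; adjusted p = 0.650 with an estimated correlation). Hspa5 and C1qb passed in 0 of the 8 fits with a heart left out (adjusted p up to 0.114 and 0.0951), and C1qb did not pass with a term for the animal series (0.0514). Cd163 was at -0.60 and Csf1r at -0.31 on the log2 scale, neither past the test. These shifts stood beside the higher mitochondrial share of the same hearts. The mean log2 value of the macrophage list overlapped between the groups (exact permutation test, p = 0.114), and that of the unfolded protein list did not (p = 0.0286, the smallest possible; adjusted 0.177 over 31 lists). The hearts also did not overlap, with the same p and adjusted p, for the lists of mitochondrially encoded genes (14.6 to 14.8), mitochondrial biogenesis (4.07 to 4.13), ion channels and junctions (4.32 to 4.21) and endothelial markers (5.56 to 5.48), each a group mean of log2 values, GFP first.

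Other cell type markers gave few calls. Of 20 endothelial markers, Aqp1, a water channel, fell 1.26-fold and 0 rose (adjusted over the list alone 1 fell; camera adjusted p = 0.1003), with Rgcc at -0.46, Fabp4 at -0.15 and Kdr at 0.17 on the log2 scale, none past the test. Of 5 skeletal muscle markers at a testable level, Casq1 fell (adjusted over the list alone 2 fell; camera adjusted p = 0.132), Mybpc2 was at -0.49, Tnni2 at -0.55 and Ckm at 0.12. No marker passed, over all genes or over the list alone, among 17 of fibroblasts (camera adjusted p = 0.974), 15 of mural cells (0.784), 7 of erythroid cells (0.166) and 8 of atrial muscle (0.733, with a median change of 0.01 and a mean of -0.06). The same held for 27 genes of TGF-beta signalling (camera adjusted p = 0.944, with a median of -0.01 and a mean of 0.00), 31 of the interferon response (0.0974), 18 of the cell cycle (0.451) and 19 immediate early genes (0.166). Among 26 insulin and Akt genes and 17 clock genes none passed over all genes, and 1 rose in each adjusted over the list alone (camera adjusted p = 0.662 for both). Lists for lymphocytes, neutrophils, epicardium, Schwann cells and neurons, adipocytes, and thymus and lung had under 5 members tested, and no member of these 6 lists passed.

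**Figure D3:**
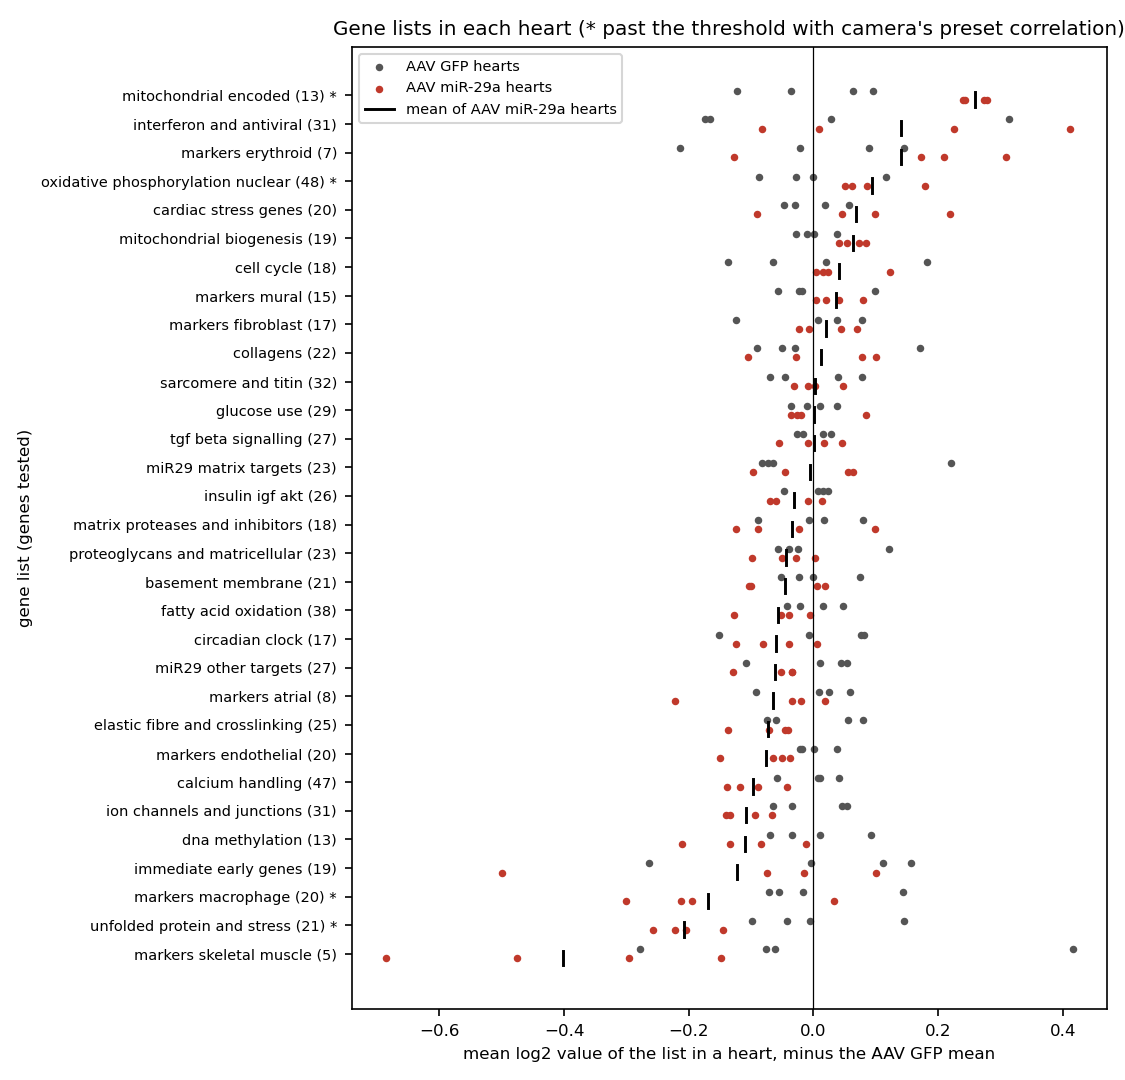
Mean log2 value of 31 gene lists in each heart, minus the mean of the GFP hearts (horizontal axis), with 1 point per heart and a bar at the miR-29a mean. The mitochondrially encoded list was highest in miR-29a hearts, at 0.26, with all 4 above the GFP hearts.

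Genes with a miR-29 seed site in the 3' UTR were lower relative to genes without a site. The median log2 fold change was -0.04 for 2392 genes with any site and 0.01 for 9113 genes with none, a difference of -0.05 (camera p = 0.00295, adjusted 0.00606 over the site sets; p = 0.0877, adjusted 0.183, with an estimated correlation). Centred within bins of abundance, GC content and 3' UTR length, a test chosen after seeing the data, the difference of means was -0.05 (camera p = 0.00718, and p = 0.000339 with an estimated correlation). Without centring, the median difference was negative in 4 of 4 miR-29a hearts. Each was set against the same mean of the GFP hearts, so these are not independent results. Of genes with a site, 67 fell and 10 rose, or 2.80% and 0.418%, against 116 and 98 of those without, or 1.27% and 1.08%. Among 389 genes with an 8mer the difference was -0.06 (camera adjusted p = 0.00606), with 10 fallen and 0 risen (adjusted p = 0.183 with an estimated correlation). It was -0.05 for 1575 genes with a 7mer-m8 as best site (adjusted p = 0.0107, and adjusted p = 0.183 with an estimated correlation) and -0.06 for 428 with a 7mer-A1, which did not pass (adjusted p = 0.0865). Among 457 genes with 2 or more sites it was -0.06 (adjusted p = 0.0107, and adjusted p = 0.217 with an estimated correlation). Changed genes named above that carry an 8mer are Bdh1, Col4a5, Dnmt3a and Lpl. Eln has 2, Col1a1, Col3a1 and Col4a1 have 1 each, and these 4 genes did not pass the test. The 10 risen genes with a site include Armh4, with 3 sites, and Atcay, with 1, none of them an 8mer. Within groups of genes by 3' UTR length, the difference was -0.10 for the shortest (camera adjusted p = 1.55e-05), -0.06 for the middle (adjusted p = 0.00285) and -0.04 for the longest (adjusted p = 0.0169). With an estimated correlation the adjusted p was 0.0369 for the shortest and the middle and 0.361 for the longest. The miR-29 heptamer gave the lowest median difference of 140 heptamers of the same base composition, at -0.05, against -0.04 to 0.03 for the 139 others. The lowest of the others, GGTGCTT at -0.043, shares the stretch GGTGCT with the miR-29 heptamer.

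**Figure D4:**
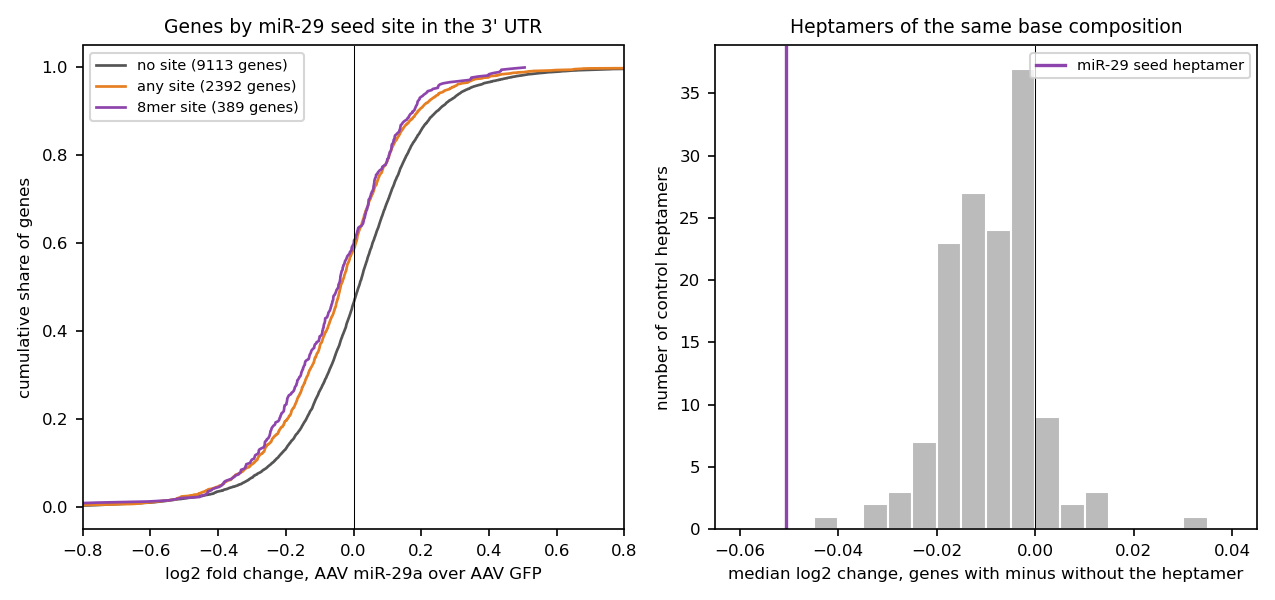
Left, cumulative share of genes (vertical axis) by log2 fold change for genes with no miR-29 seed site (9113), any site (2392) and an 8mer (389). Right, number of control heptamers by the median log2 difference between genes with and without each, where the line marks the miR-29 heptamer at -0.05, below all 139 controls.

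The authors' deposited table called 515 of 13448 genes by the Wald test at q under 0.05, 226 higher and 289 lower, and 227 by the likelihood ratio test. Of 11749 genes in both that table and the limma fit, 295 were changed by limma and 503 by the authors' Wald q-value, and 276 were shared, all with the same sign, where 12.6 would be shared by independent lists. Both tests use the same 8 hearts. In the authors' deposited table Timp1 had a Wald q-value of 0.0301 and Casq2 of 0.0272, and neither gene passed in limma. By the authors' likelihood ratio test their q-values were 0.116 and 0.113, so neither passed there. Its log2 effects were -2.18 for Acta1, -0.91 for Col4a5 and 0.66 for Slc8a1.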

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

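The tests of technical explanations and the counts of splits in this part were chosen only after the results they measure were seen. The seed site test centred within bins, and its count of splits, were run after the count for the test as planned was known. Within each group of 4 hearts, the gap of the highest or lowest value to its nearest neighbour was set against the whole range in 244 groups of values. In 12 of these groups 1 heart stood apart, and chance gives about 12.2, or 1 in 20 groups. Scaled reads per base stood apart for Gm10241 in GFP replicate 1 (1.83, with 0 in the others), Eno3 in miR-29a replicate 1 (1641, others 1411 to 1449) and Col4a1 in GFP replicate 3 (159, others 118 to 123). Cpt2 in miR-29a replicate 2 was at 102.3 (others 90.3 to 92.2), Pdk4 in miR-29a replicate 3 at 55.9 (40.9 to 43.2) and Trim63 in GFP replicate 1 at 92.7 (99.7 to 100.5). Col4a5 in GFP replicate 3 was at 12.8 (9.99 to 10.4), Lypd8l in miR-29a replicate 4 at 7.89 (2.98 to 3.33) and Acta1 in miR-29a replicate 1 at 61.4 (32.1 to 35.1). Of mean log2 values of lists, the matrix targets in GFP replicate 3 were at 4.45 (others 4.14 to 4.16), glucose use in miR-29a replicate 1 at 7.43 (7.31 to 7.33) and cell cycle in miR-29a replicate 3 at 2.47 (2.35 to 2.37).

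The number of changed genes, 296, was reached by 1 of the 35 splits of the 8 hearts into 4 and 4, the real one. The highest other split gave 2. The real split's share of the splits, 0.0286, is the smallest that 35 allow. The other splits mix the groups, so a group difference can itself lower their counts. The count stood apart from the other splits, but chance cannot be fully excluded for it. The real split called 4 gene lists, and 24 of the 35 splits called as many, up to 12, so chance cannot be excluded for the number of lists called at camera's preset correlation.

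Genes with miR-29 seed sites were lower in miR-29a hearts. A difference in 3' UTR length, GC content or abundance would have lost most of its size when values were centred within bins of these properties, and 88.9% of the mean difference remained. The miR-29 heptamer ranked 1 of 140 heptamers of the same base composition, and 2 after adjustment for the same properties, which argues against a property of such heptamers in general. The heptamer ahead of it after adjustment, GGTGCTT, shares the stretch GGTGCT with it and is not an unrelated control. Of the 35 splits, 4 gave a seed site p as small as the real 0.00295, down to 0.000179, so chance cannot be excluded for the test as planned, while 1 split, the real one, did so after centring (0.00718, the smallest other 0.0262). Repression by the delivered miR-29a stays open as a hypothesis.

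Mitochondrially encoded transcripts were higher in miR-29a hearts. A factor applied to a whole heart by the authors cannot change a share within that heart, and the lowest mitochondrial share among miR-29a hearts lay 1.51 percentage points above the highest among GFP hearts. A larger amount of cardiomyocyte RNA would raise sarcomere genes alike. Their median change, 0.02 on the log2 scale, lay 0.24 below that of the mitochondrially encoded genes. That gap lay within the SD of the sarcomere changes, 0.44, and beyond their scaled median absolute deviation, 0.20. Without Acta1 the SD was 0.19, so the gap exceeded both, and the wider SD rests on that 1 gene. Of these genes 19 were higher and 13 lower, and Mybpc3, at 0.45, rose by more than the mitochondrial median of 0.26. The mean log2 values of endothelial and macrophage markers were lower by 0.08 and 0.17, as a larger share of cardiomyocyte RNA would give, while those of fibroblast and mural markers were higher by 0.02 and 0.04. These values point both ways, so a larger amount of cardiomyocyte RNA stays open, and differences in RNA capture between libraries were not tested. A technical source stays open too, beside an effect of miR-29a.

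Acta1 and Casq1, genes of skeletal muscle, were lower in miR-29a hearts. Skeletal muscle carried into the GFP hearts would bring its other abundant transcripts, and the summed excess of 9 of them (Myh1, Myh2, Myh4, Tnnt3, Tnni2, Tnnc2, Mylpf, Actn3 and Pvalb) in GFP hearts was 0.531 scaled reads per base, 0.373% of the excess of Acta1, 142. Reads shared with other actins are a poor candidate, since 2.02% of the 50-base stretches of Acta1 and 0 of Casq1 occur in another gene. A change within heart cells stays open as a hypothesis, and its cause was not tested.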

How the results depend on the processing

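The 50 changed genes that the naming rule takes kept their sign under each alternative run, and 15 of them passed with each heart left out. Genes called changed, with higher and lower genes in brackets, were 96 (32 and 64) with no filter on low values, where more genes were tested, 79 (27 and 52) without the trend, and 515 (226 and 289) by the authors' q-values. Leaving out a heart, which also removes a sample, gave 55 to 264 (17 to 114 and 38 to 158). Chosen after seeing the data, the same total in each heart gave 1279 (58 and 1221), and the same total without mitochondrial genes 404 (62 and 342), where the median change was -0.07 on the log2 scale. The share of higher genes, 37.5% as deposited, was 4.53% and 15.3% in these. The same total scales down miR-29a hearts, whose totals were higher, relative to GFP hearts, and the median change moved from 0.00469 to -0.15. The planned TMM and median-of-ratios rescalings gave 294 (106 and 188) and 296 (109 and 187). Why the other counts moved was not tested further. The number of lists called was 4, and 7 with the same total, both with and without mitochondrial genes. It was 4 to 7 with a heart left out (7 without miR-29a replicate 4), 0 with an estimated correlation and 2 by fry. Nuclear oxidative phosphorylation genes turned down with the same total (adjusted p = 0.784), and had an adjusted p of 0.650 with an estimated correlation and 0.275 by fry. With an estimated correlation the adjusted p was 0.418 for mitochondrially encoded genes, 0.40004 for the unfolded protein list and 0.650 for macrophage markers (0.249 by fry). Leaving out a heart, the list of other miR-29 targets had adjusted p from 0.0464 to 0.3004. The seed site shift lost its call with an estimated correlation (p = 0.0877). Apart from fry, it passed under its other alternatives, with camera p from 5.15e-06 (shortest 3' UTRs only) to 0.0347. With values centred within bins, chosen after seeing the data, it passed with an estimated correlation as well (p = 0.000339). Fry, which tests the site genes alone and not their difference from other genes, gave 0.0584. The causes were not tested. A term for the first part of the animal number, whose meaning the labels do not give, gave 239 changed genes, 210 of them among the 296. Of the genes that the naming rule takes, it ended the calls of Tfrc, Dnmt3a, Rcan1, Hspb7, Pdk4, Pgam1 and C1qb. Count models were not run because whole reads were not recovered, and without counts the precision of low genes is not known.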

Other observations

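The values in this part were chosen after the data were seen. Of the 10 genes with a miR-29 8mer that fell, 5 not described so far are given here. Narf was 28.2 ± 2.20 scaled reads per base in GFP hearts and fell by 0.76 on the log2 scale. Ak3, a mitochondrial adenylate kinase, fell by 0.43, Igsf1 by 0.55, Bak1, a promoter of apoptosis, by 0.45 and Sh3glb1 by 0.31. Against genes with no site, genes with an 8mer held more fallen genes (Fisher's exact test across genes, two-sided, p = 0.0387) and fewer risen genes (p = 0.035), and genes are not independent replicates. Singled out after the values were seen, Alas1, the first enzyme of haem synthesis, rose from a mean of 217 to 349 (limma adjusted p = 0.00990), and Fth1, ferritin heavy chain, was at means of 1406 and 1447 (adjusted p = 0.793).

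Some processed pseudogenes had large and uneven values that passed no test. Gm14303 was listed at 0 in GFP replicates 1 and 2, at 72 and 57.3 in GFP replicates 3 and 4, and at 25.9, 158, 57.7 and 189 in the miR-29a hearts (limma adjusted p = 0.282). Gm28900 ranged from 0 to 50.4 in GFP hearts and from 9.44 to 95.5 in miR-29a hearts (adjusted p = 0.275).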
